A study of Caenorhabditis elegans with 2 samples.

How the data were processed

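The series compares whole Caenorhabditis elegans of strain N2 given vehicle (dimethyl sulfoxide in Escherichia coli OP50) with worms given 100 µM ellagic acid (EA), both at day 5. Groups were taken from the sample titles, and the columns of the deposited table were matched to samples by the column names that the sample descriptions give. Each group has 1 library. Per the labels' protocols, libraries were made from 1 µg of total RNA with the NEBNext Ultra RNA kit. Whether counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

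The authors deposited raw counts per gene for both libraries, and 21163 gene rows were present: 19984 from the annotation and 1179 gene models that the authors added. Per the labels' protocols, the reference was assembly WBcel235 and expression was estimated as FPKM, a value scaled by transcript length and sequencing depth, which the authors deposited beside the counts. The deposited table also holds the authors' log2 ratio, false discovery rate and call per gene. The submitters' processing notes name edgeR, without a version. The aligner and the counter are not given in the sources used here. How reads matching several genes were counted is likewise not given, so members of near-identical gene families are reported as uncertain.

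The counts were the basis of all values computed here. Effective library sizes came from the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, and gave scaling factors of 0.988 for control and 1.01 for EA. They served to compute CPM (counts scaled to library size) and a log2 ratio of EA to control with 0.5 added to each count. At these depths 5 CPM corresponds to 207 counts in the control library and 200 counts (199.5) in the EA library. The 95% interval of each ratio is the exact conditional binomial (Clopper-Pearson) interval. Its median width over genes at 5 CPM or more was 0.21 on the log2 scale. Such intervals cover counting error only, not the spread between cultures or libraries. A count of 0 allows up to 0.0726 CPM in the control library and 0.0752 CPM in the EA library, the level of 3 counts.

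Because 1 library per group leaves no estimate of the spread, no test across genes was run and no p-value was computed. Genes were described by a size rule fixed before the data were examined: a mean of at least 5 CPM, a ratio of at least 2-fold and a 95% interval excluding 1. For 46 gene lists fixed at the same time, the members at a mean of at least 1 CPM were counted by the same fold and interval rule, and the median log2 ratio was placed as a percentile among 10000 random lists of the same size. Random lists were matched on mean expression in 20 bins and, as an alternative fixed at the same time, on expression and transcript length in 10 by 10 bins. They could draw the list's own members, so a list that fills much of its bins is compared partly with itself. The percentile describes these 2 libraries. Of the names in the lists 31 matched no row, and 2268 list entries did. Annotation groups of 10 to 300 members from the deposited table were placed in the same way. The 95% counting interval of a list's median came from 500 Poisson redraws of the counts. The bootstrap 95% intervals of the closing section resampled the genes of a list within these 2 libraries. They treat genes as independent, which genes regulated together or sharing reads are not, and do not cover the spread between cultures.

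Genes named in the text follow a rule fixed before the data were examined: the 12 largest and 12 smallest log2 ratios among genes at a mean of at least 10 CPM whose interval excludes 1, the 5 largest gains and 5 largest losses in CPM, up to 4 members of each list with the largest absolute log2 ratio at 5 CPM or more, and a fixed set of insulin/IGF-1 pathway, stress and yolk protein genes. The result of 1 gene of this set is not reported here. The male-specific marker genes of the closing section are an added list. Of the annotated rows 19979 matched the RefSeq gene table of WBcel235, which gave coordinates, counted from 1. Transcript length is the longest annotated transcript in the Ensembl annotation of WBcel235, known for 19973 rows; for genes of the mitochondrial DNA the gene span was used. No genome sequence was used here, so GC content was not checked.

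The steps were tested on simulated data for the comparison of EA with control. Counts were drawn with counting error only from the real means and library sizes, with 200 genes changed, 50 per fold. No spread between cultures or libraries was simulated, so calls among unchanged genes say nothing on false calls from such spread. The size rule, run on 10574 genes, recovered 47 of 50 genes changed 2.5-fold, 45 of 50 changed 3-fold and 47 of 50 changed 4-fold, called 0 of 50 changed 1.5-fold, and called 0 of 10391 unchanged genes. The intervals held the simulated ratio for 95.4% of unchanged genes. With a simulated length trend over 13779 genes, 99 of 100 lists of short genes without a shift fell below percentile 2.5 when matched on expression, and 4 of 100 did when length was matched too. Lists shifted by 0.4 lay above percentile 97.5 in 99 of 100 draws with length matched.

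Alternatives fixed before the data were examined were DESeq2 1.42.0 median-of-ratios size factors, total counts, upper quartile scaling, library size without the 20 most abundant genes, the deposited FPKM with 0.1 added, a prior count of 5, the deeper library thinned to the depth of the other, minimum means of 1 and 20 CPM or none, folds of 1.5 and 4, no interval rule, leaving out germline, embryo and yolk protein lists, other minimum levels for list members, and the mean in place of the median. Added after seeing the data were the removal of a lowess trend (fraction 0.3) of the log2 ratio on log2 transcript length, the daf-16 dependent list without heat shock list members and the heat shock list without near-identical copies. The trend was fitted on genes at a mean of at least 5 CPM and then removed from all genes of known length. Analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.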

Results

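Gene expression was measured by RNA sequencing in whole Caenorhabditis elegans of the wild-type strain N2 at day 5. Worms received the vehicle dimethyl sulfoxide or 100 µM ellagic acid (EA), a plant polyphenol, mixed into their food, the Escherichia coli strain OP50. The control group and the EA group held 1 library each. The control library contained 41840364 counts and the EA library 39421614 counts over 21163 gene rows. With 1 library per group, no difference given here has a replicate check, and the intervals cover counting error only. The series title names longevity, healthspan and the insulin/IGF-1 signalling pathway, so the comparison asks which transcripts differed with EA, in that pathway and beyond it.

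Transcripts of acs-2, sodh-1, infection response genes and small heat shock genes were among those lower with EA, and transcripts of sperm genes were among those higher. Of 10610 genes at a mean of at least 5 CPM, counts scaled to library size, 51 were at least 2-fold higher and 161 at least 2-fold lower with EA, each with a 95% counting interval of the ratio that excluded 1. The interval added little to the 2-fold limit, since its largest half-width at 5 to 6 CPM was 0.396 on the log2 scale. These 212 genes made up 2.00% of the genes assessed, and 24.1% of them were higher. Most genes differed little, with a median log2 ratio of 0.01 and a central 95% of genes between -0.85 and 0.57. The higher genes were weakly expressed, with a median of 8.01 CPM against 12.9 CPM for the lower genes. At a minimum mean of 20 CPM, 1 gene was higher and 52 were lower. After a trend on transcript length was removed, an alternative added after seeing the data, the numbers were 70 higher and 100 lower, or 41.2% higher.

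**Figure D1:**
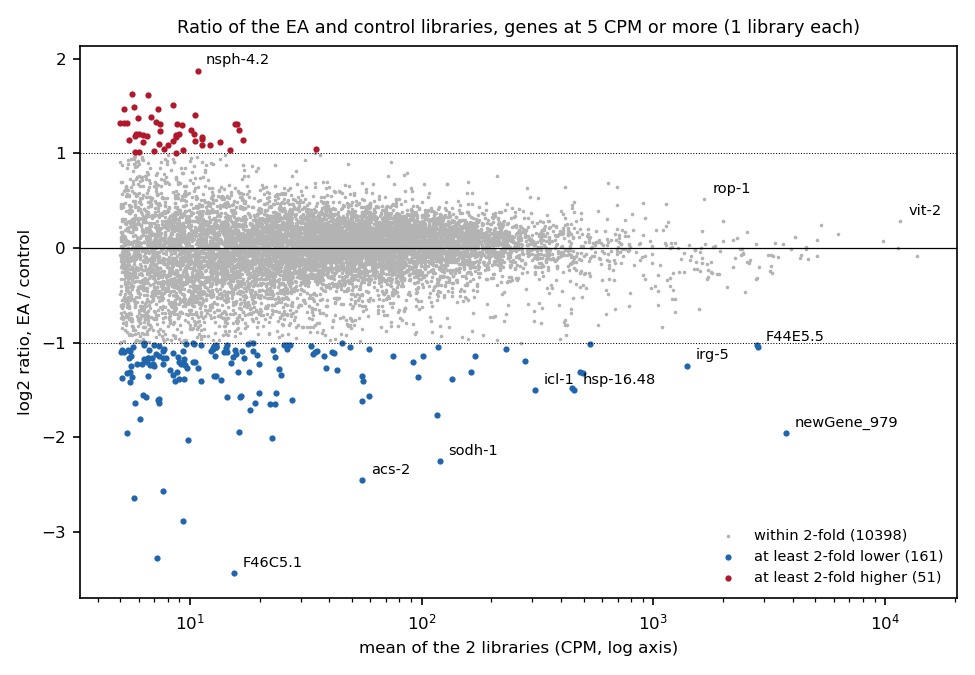
Each point is a gene with a mean of at least 5 CPM, with its mean over the 2 libraries in CPM on a log axis and its log2 ratio of EA to control. The 51 genes at least 2-fold higher lie at low expression, while the 161 lower genes include abundant ones such as irg-5 and F44E5.5.

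Among genes at a mean of at least 10 CPM, the lower ones were led by F46C5.1 (chromosome II, 8820153 to 8821190, build WBcel235), at 28.4 CPM in the control library and 2.61 CPM with EA, which is 10.9-fold lower (95% counting interval 8.91 to 13.4). Next came acs-2, an acyl-CoA synthetase of mitochondrial fatty acid oxidation (chromosome V, 15567394 to 15569897), at 93.8 CPM in the control and 17.1 CPM with EA, 5.48-fold lower (5.05 to 5.95). The alcohol dehydrogenase gene sodh-1 (chromosome V, 11888248 to 11889650) was 4.77-fold lower (4.52 to 5.03), at 198 and 41.6 CPM. The patched-related gene ptr-22 was 4.02-fold lower (3.58 to 4.53). Lower by at least 3-fold were also ZC262.7, Y94H6A.10, Y73F4A.1, F56A4.2, nspc-6, C06B3.6 and clec-209, with log2 ratios from -1.94 to -1.62. With the length trend removed these ranged from -1.61 to -1.47, except for the short nspc-6, which ended just under 2-fold at -0.99. F56A4.2 (1456 and 447 counts) and clec-209 (1392 and 427) have equal transcript lengths of 891 nucleotides. They may be copies that share reads, so their single values are uncertain. The gene model newGene_979, which the authors added and which has no name or position in the table, took 245936 counts in the control library and 61011 with EA, 3.89-fold lower. It held 0.588% of the control counts and 0.155% of the EA counts (exact binomial 95% intervals 0.585% to 0.590% and 0.154% to 0.156%).

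At the same minimum the higher genes were led by nsph-4.2 (chromosome IV, 5218796 to 5220169), at 191 and 678 counts, 3.67-fold higher with EA (3.13 to 4.34). It belongs to a family of similar nematode-specific peptides, so its reads can be shared with copies. Y57G11A.2 was 2.64-fold higher (2.28 to 3.09), and Y38C1AA.7 was 2.49-fold higher (2.20 to 2.82). The sperm chromatin gene spch-3 was 2.37-fold higher (2.11 to 2.67), the Argonaute gene alg-4 2.25-fold higher (1.96 to 2.60) and ssq-4, a sperm-specific gene, 2.18-fold higher (1.92 to 2.48). C33F10.1, F17E9.5, F32A11.3, Y43F8B.14 and the added models newGene_1145 and newGene_1255 had log2 ratios from 1.13 to 1.31. In absolute terms the largest gain was that of the yolk protein gene vit-2, from 10451 to 12720 CPM. The other large gains were vit-6, vit-5, rop-1, which encodes a Ro RNA-binding protein, at a log2 ratio of 0.51, and the elongation factor gene eef-2 at 0.08. The largest absolute losses were newGene_979, F44E5.5, F44E5.4, irg-5 and the ribosomal protein gene rpl-27.

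No gene of the insulin/IGF-1 pathway core differed by 2-fold. The 18 measured members had a median log2 ratio of -0.03, with 8 above 0 and 10 below. The receptor gene daf-2 (chromosome III, 2994514 to 3040846) had 127 CPM in the control and 115 CPM with EA, a log2 ratio of -0.15 (95% counting interval -0.20 to -0.09). The forkhead transcription factor gene daf-16 (chromosome I, 10750498 to 10776703) had 180 and 175 CPM, a log2 ratio of -0.04 (-0.09 to 0.01). Among the kinase genes, age-1 had a log2 ratio of 0.18, sgk-1 of 0.14, pdk-1 of 0.10, akt-1 of -0.02 and akt-2 of -0.28. The insulin receptor substrate gene ist-1 had -0.46 (-0.65 to -0.28) and hcf-1, a regulator of daf-16, had 0.25 (0.21 to 0.30). The list's median lay at percentile 15.96 of 10000 random lists matched on expression and at percentile 2.28 when transcript length was matched too, and its sign turned under other scalings. Of 19 measured insulin-like peptide genes 1 was at least 2-fold higher and 1 lower. Their median was -0.32, at percentile 6.80 and, with length matched, 46.2, and it was -0.05 with the length trend removed. Here ins-7 had -0.59 and daf-28 had -0.32.

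**Figure D2:**
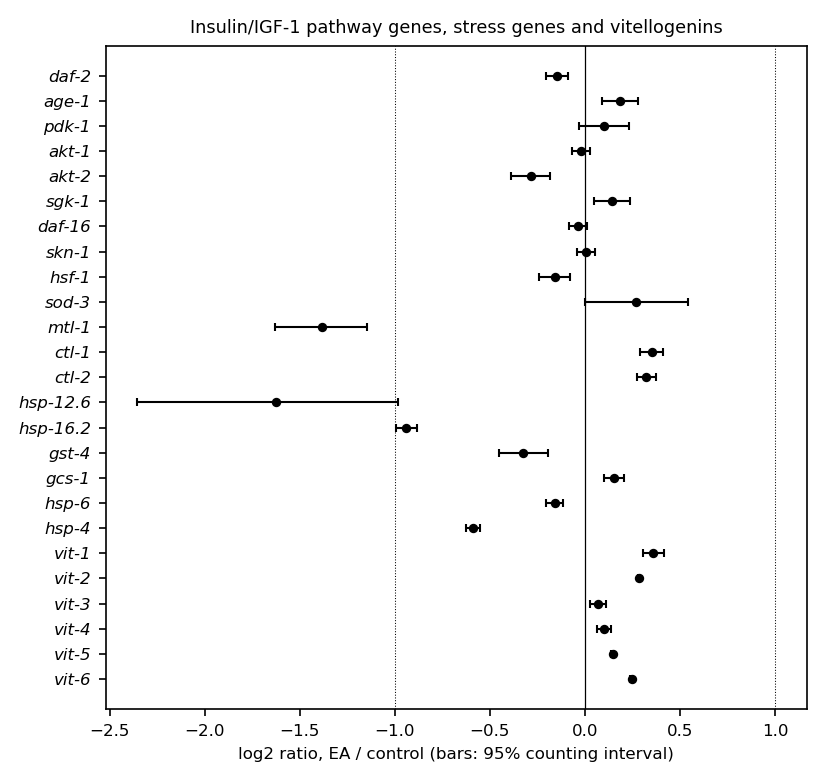
Points are log2 ratios of EA to control for insulin/IGF-1 pathway genes, stress genes and yolk protein genes, with 95% counting intervals as bars and dotted lines at 2-fold. Of the pathway genes shown, akt-2 lies lowest at -0.28 and age-1 highest at 0.18, and mtl-1 and hsp-12.6 lie below -1.

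Genes known to be higher in daf-2 mutants in a daf-16 dependent manner were lower as a list with EA. Of 23 measured members, 10 were at least 2-fold lower and 0 were higher, and the median log2 ratio was -0.53. That median lay below all 10000 lists matched on expression and at percentile 0.04 with length matched. With the length trend removed it was -0.31. The lower members included icl-1, an enzyme of the glyoxylate cycle (455 and 161 CPM, 2.83-fold lower, 2.75 to 2.91), the metallothionein gene mtl-1 (536 and 198 counts, 2.61-fold lower, 2.22 to 3.09, but at a log2 ratio of -0.86 and so under 2-fold with the length trend removed) and hsp-12.6 (81 and 25 counts, 3.09-fold lower, 1.98 to 5.11). The superoxide dismutase gene sod-3 had 213 and 248 counts, a log2 ratio of 0.27 with an interval from 0.00 to 0.54, and the catalase genes ctl-1 and ctl-2 had 0.35 and 0.32. Many members also stand on the heat shock list. The 14 that do not had a median of -0.15, at percentile 12.5 with length matched.

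Of 17 measured genes known to be lower in daf-2 mutants, 3 were at least 2-fold lower with EA and 0 higher, with a median of 0.07 at percentile 86.9 (92.8 with length matched) and a mean of the opposite sign, -0.20. The lower ones included lips-11 at -1.07 and dod-24, at 60.4 CPM in the control and 30.2 CPM with EA. Both ended just under 2-fold, at -0.99, with the length trend removed, and dod-24 also did under most other scalings. All 6 yolk protein genes, which are in this list too, had ratios above 0, from 0.07 for vit-3 to 0.36 for vit-1, and none reached 2-fold. Their median of 0.20 lay at percentile 99.0 of lists matched on expression and 99.9 with length matched. Together they took 2.16% of the control counts and 2.60% of the EA counts. The genes vit-3, vit-4 and vit-5 are similar in sequence, so their single values are uncertain.

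Heat shock transcripts were lower with EA. Of 26 measured members, 8 were at least 2-fold lower, 0 were higher, and 25 had a ratio below 0. The median of -0.53 lay below all 10000 random lists, with or without matching on length. The list held 1.52% of the control counts and 0.873% of the EA counts. The inducible hsp-70 genes F44E5.4 and F44E5.5 (chromosome II, 11757107 to 11759311 and 11759662 to 11761861) were 2.04-fold and 2.06-fold lower, both just under 2-fold with FPKM. The small heat shock genes hsp-16.48, hsp-16.49 and hsp-16.11 on chromosome V were 2.83-fold, 2.80-fold and 2.49-fold lower, the last at -0.94 on the log2 scale with the length trend removed. These genes are near-identical pairs, so reads cannot be assigned to a single copy with certainty. The co-chaperone gene dnj-13, which is not such a copy, was 2.49-fold lower (2.39 to 2.58). Without the genes that have near-identical copies, the median of the other 18 members was -0.20. hsp-16.2 had a log2 ratio of -0.94, and the transcription factor gene hsf-1 had -0.16.

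Other stress lists moved less than the full heat shock list. Without near-identical copies, though, the heat shock median of -0.20 was near that of the metal handling list, -0.22. The 21 genes of the endoplasmic reticulum unfolded protein response had 0 members past 2-fold and a median of -0.04, at percentile 13.9 and, with length matched, 0.89, and the median turned to 0.04 with FPKM. Within it hsp-4 had -0.59 and the calreticulin gene crt-1 had -0.45. The mitochondrial unfolded protein response list had a median of -0.03 at percentile 16.99, with hsp-6 at -0.16, and the hypoxia list had -0.11 at percentile 21.03 (-0.04 with FPKM), with 0 members past 2-fold in either list. Among superoxide and peroxide defence genes 1 of 27 was lower, and the median was -0.11, at percentile 41.2 with length matched, and it turned to 0.11 with the length trend removed. Metal handling genes had 2 of 20 members lower, mtl-1 and mtl-2, a median of -0.22 and percentiles of 0.59 and, with length matched, 1.69. With the length trend removed the median was -0.14, and mtl-1 at -0.86 and mtl-2 at -0.50 were under 2-fold. The ferritin gene ftn-1 had -0.87.

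Phase II and glutathione S-transferase genes were lower as lists with EA, and ABC transporter genes were higher. The 22 phase II genes linked to the transcription factor SKN-1 had 2 members lower, dhs-8 at -1.29 and ugt-13 at -1.09, and a median of -0.26 at percentile 0.49 (1.02 with length matched), or -0.11 with the length trend removed. Their regulator gene skn-1 had a log2 ratio of 0.01. Here gst-4 had -0.32 and gcs-1 had 0.15. Of 40 glutathione S-transferase genes 3 were lower and 0 higher, with a median of -0.30 at percentile 0.10 (0.55 with length matched), or -0.17 (-0.175) with the length trend removed. Cytochrome P450 genes had 4 of 53 members lower, including cyp-13A5 at -1.12, and a median of -0.10 at percentile 7.42 (1.23 with length matched), or -0.06 with FPKM. UDP-glycosyltransferase genes went both ways, with 7 of 61 lower and 2 higher and a median of -0.13 (-0.125) at percentile 3.25 (0.22 with length matched). This median was -0.06 with FPKM and -0.03 over members at 10 CPM or more. ugt-8 was 7.40-fold lower (5.95 to 9.40), and ugt-30 was 2.29-fold higher (1.95 to 2.70). The ABC transporter list had a median of 0.16 at percentile 99.9 (99.8 with length matched) and a mean of 0.07 (0.075), although pgp-12 had -0.74 and pgp-14 had -0.69.

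Fat breakdown genes had a median above that of other genes, while some of their members were far lower. Of 47 measured genes 3 were at least 2-fold lower and 1 higher, and the median of 0.18 lay above all 10000 lists matched on expression and at percentile 99.9 with length matched. Their mean was 0.05. The lower members were led by acs-2, and the lipase-like genes lips-11 and lips-10 had -1.07 and -0.95, while ech-1.1, an enzyme of beta-oxidation, had 0.94. Fat synthesis genes had 0 of 30 past 2-fold and a median of 0.03 at percentile 55.2. The desaturase genes fat-6 and fat-7 had -0.98 and 0.44. Among lipid-binding protein genes 2 of 16 were lower, including far-7 at 4.10-fold (3.44 to 4.93), and the median was -0.33 at percentile 0.01, or 9.53 with length matched, and -0.13 with the length trend removed. Of 40 glycolysis, citric acid and glyoxylate cycle genes 1 was lower, icl-1, and the median was 0.04 at percentile 49.2. The propionate and methionine cycle list had a median of -0.06 at percentile 4.29 (0.88 with length matched), with sams-1 at -0.55 and sams-5 at 0.76. Energy sensing genes of the AMPK and TOR pathways had a median of -0.01 at percentile 18.3. Autophagy and lysosome genes had 1 of 75 lower and a median of -0.14, below all random lists, or -0.08 with FPKM. Within that list lipl-5 had -0.81 and the cathepsin gene cpr-4 had -0.77.

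Infection response transcripts were lower with EA, with 4 of 20 members at least 2-fold lower and 0 higher. The median was -0.31, below all random lists with or without length, and it was -0.12 over members at 10 CPM or more. irg-5 (chromosome V, 13737010 to 13738474) had 1969 CPM in the control and 832 CPM with EA, 2.37-fold lower (2.34 to 2.4), and irg-4 was 2.07-fold lower (1.98 to 2.16), just under 2-fold with FPKM. dod-24, also on this list, stood at the limit of 2-fold. Lysozyme, caenacin and saposin genes had 9 of 42 members lower and 0 higher, with a median of -0.54, below all lists matched on expression and at percentile 0.12 with length matched, or -0.24 with the length trend removed. Of these, fipr-1 was 5.94-fold lower (4.76 to 7.56) and cnc-3 2.23-fold lower (1.88 to 2.67), with log2 ratios of -2.07 and -0.74 with the length trend removed. C-type lectin genes had 13 members lower and 3 higher, with a median of -0.06 at percentile 25.2. The 77 genes with a C-type lectin domain in the deposited annotation had a lower median, -0.14, at percentile 1.13 (1.04 with length matched). Of these, 13 were lower and 2 higher. Among the lower lectins, clec-13 (552 and 226 counts) and clec-15 (548 and 226) may be copies that share reads. clec-17 was 2.95-fold lower (2.76 to 3.15). The intracellular pathogen response list had 4 of 26 lower and a median of -0.22 at percentile 3.75 (3.82 with length matched), which turned to 0.21 (0.205) over members at 10 CPM or more, with pals-23 at 0.60 and pals-39 at -0.62.

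Germline transcripts were higher with EA, those of sperm most. Of 58 measured sperm genes 20 were at least 2-fold higher and 0 lower, and 54 had a ratio above 0. The median of 0.80 lay above all 10000 random lists, with or without matching on length, and it was 1.21 with the length trend removed. ssq-3, gsp-3 and gsp-4, the latter pair encoding sperm phosphatases, had log2 ratios of 1.32, 1.203 and 1.202, at 2.85 to 12.5 CPM. These transcripts were scarce, and the list took 0.0409% of the control counts and 0.0555% of the EA counts. Only 10 members had a mean of at least 10 CPM, and their median was 0.17. The sperm-specific msp, nspd and ssp genes of the list are multi-copy families with shared reads. Their summed counts were 3541 and 5997, a ratio of 1.75 (1.68 to 1.83), and the 24 measured members outside them had a median of 0.36. Whether members outside these families, such as gsp-3 and gsp-4, also share reads was not checked. The 30 oocyte and eggshell genes had a median of 0.35 and the 40 germline and meiosis genes one of 0.23, both above all random lists and with 0 members past 2-fold. oma-2, an oocyte maturation gene, had a log2 ratio of 0.68, puf-6 had 0.66, and the chromosome axis gene htp-3 had 0.45. Early embryo genes had a median of 0.09 at percentile 85.7. Histone genes had 1 of 23 higher and 2 lower, a median of 0.04, and a percentile of 70.1 or, with length matched, 99.8.

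**Figure D3:**
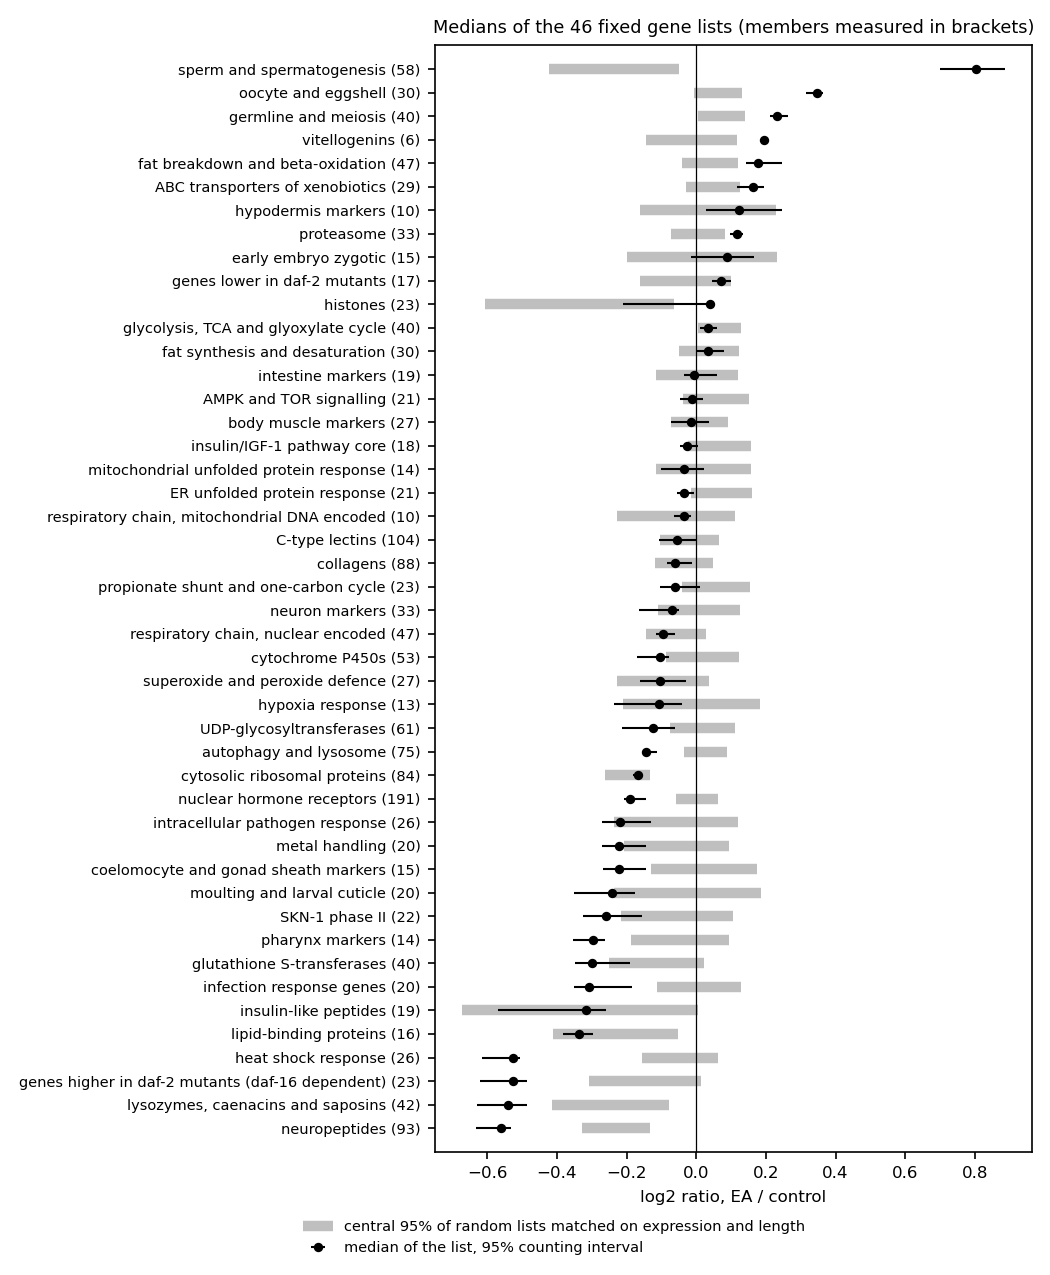
Points are median log2 ratios of EA to control for the 46 gene lists, with 95% counting intervals as lines and the central 95% of random lists matched on expression and length as grey bars. The sperm list at 0.80 and the neuropeptide list at -0.56 mark the ends, each outside its grey bar.

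Neuropeptide transcripts were lower with EA, with 16 of 93 at least 2-fold lower and 0 higher. The median was -0.56, below all random lists with or without length. nlp-27 and nlp-31, which are induced by infection in the epidermis, were 2.99-fold (2.62 to 3.43) and 2.66-fold lower (2.29 to 3.09), and nlp-3 was 2.14-fold lower (1.89 to 2.43). With the length trend removed the list's median was -0.38, and nlp-27 at -0.96, nlp-31 at -0.997 and nlp-3 at -0.77 were under 2-fold, since all 3 transcripts are short. General neuron markers had 0 of 33 past 2-fold and a median of -0.07 at percentile 17.2 (9.24 with length matched), with egl-3, a neuropeptide processing enzyme, at -0.46. All 14 measured pharynx markers had ratios below 0, with a median of -0.30 at percentile 0.01 (0.11 with length matched), and phat-8 had -0.89. Coelomocyte and gonad sheath markers had 2 of 15 lower, including cup-4 at -1.36, and a median of -0.22 at percentile 1.15 (0.16 with length matched), or -0.08 over members at 10 CPM or more. Intestine, body muscle and hypodermis markers had medians of -0.01, -0.02 and 0.12, at percentiles 41.8, 14.6 and 87.9. Collagen genes had 4 of 88 lower and a median of -0.06 at percentile 22.1, and moulting and larval cuticle genes had 0 of 20 past 2-fold and a median of -0.24 at percentile 5.07 (2.24 with length matched). Nuclear hormone receptor genes had 5 of 191 lower and a median of -0.19, below all random lists, or -0.10 (-0.095) with FPKM, with nhr-263 at -1.09.

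Short transcripts had lower ratios than long ones, apart from some groups such as sperm and histone genes. The median log2 ratio was -0.72 for the 30 genes under 300 nucleotides of annotated transcript and -0.59 for the 133 genes from 300 to 400, against 0.04 for the 2002 genes from 1500 to 2000. Spearman's rho between length and ratio was 0.268 across 10426 genes, which are not independent replicates. Among genes under 600 nucleotides 66 of 778 were at least 2-fold lower and 2 higher, and among longer genes 93 of 9648 were lower and 46 higher. Ribosomal protein genes followed this trend. Their median was -0.17, below all lists matched on expression but at percentile 81.3 with length matched, and 0 of 84 passed 2-fold. The matched lists could draw these genes themselves, so that percentile alone cannot tell the length trend from a ribosomal difference. In the class from 400 to 500 nucleotides, 23 ribosomal protein genes had a median of -0.30. All 265 genes of that class, these included, had -0.37. With the length trend removed the median of the ribosomal list turned to 0.09. The 13 shortest, under 400 nucleotides, had a median of -0.67, with rps-28 at -0.80 and rpl-43 at -0.78, and the 19 of at least 700 nucleotides had a median of -0.01. Nuclear genes of the respiratory chain had a median of -0.10, at percentile 0.10 but 19.3 with length matched. Genes of the mitochondrial DNA had -0.04 at percentile 29.6. Proteasome genes had a median of 0.12 at percentile 98.6 (99.8 with length matched), or 0.19 with FPKM, with rpt-3 at 0.27.

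**Figure D4:**
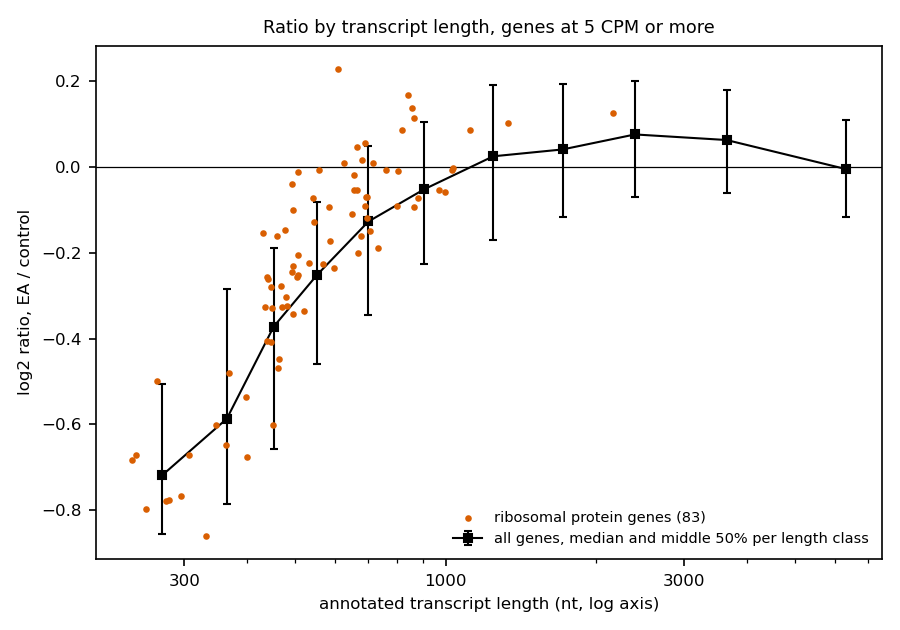
Squares are median log2 ratios of EA to control by annotated transcript length in nucleotides on a log axis, with bars for the middle 50% of genes, and orange points are ribosomal protein genes. The medians run from -0.72 in the shortest class to 0.08 in the class from 2000 to 3000 nucleotides.

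Over the 46 lists, 12 medians lay below percentile 2.5 and 7 above percentile 97.5 under both kinds of matching, against 1.15 expected on each side by chance for a single kind of matching and independent lists. Lists share members, so these numbers are not independent. Several medians near 0 changed sign with FPKM, to 0.04 for the mitochondrial unfolded protein response, 0.05 for AMPK and TOR genes, 0.03 for genes of the mitochondrial DNA, 0.06 for intestine markers and 0.07 for body muscle markers. Those of collagens, C-type lectins and the propionate and methionine cycle came to 0.01. The histone list had a mean of -0.11. Among 121 KEGG pathways in the deposited annotation, 32 lay below percentile 2.5 and 11 above 97.5 with length matched, where 3.03 on each side would be expected. Among 1152 Gene Ontology groups the balance was the reverse, with 73 below and 109 above against 28.8 expected on each side. Pathways and groups share genes too, and these expected numbers hold for independent groups only. Fatty acid degradation had a median of 0.25 over 57 genes and the peroxisome pathway 0.19 over 89 genes, both above all random lists. The pathway named drug metabolism by cytochrome P450 had -0.26 over 111 genes, with 13 at least 2-fold lower and 0 higher. It holds more than P450 genes, since the P450 list had 53 measured members, with a median of -0.10 at percentile 7.42 (1.23 with length matched). The lysosome pathway had -0.10 over 210 genes, and the pathway of longevity regulation in multiple species had -0.13 over 61 genes, with 7 lower and 0 higher, at percentile 0.04. The worm pathway of longevity regulation had -0.06 over 113 genes, with 9 lower and 0 higher, at percentile 3.99. Overlap of these 2 longevity pathways with the heat shock list was not checked, so they may repeat its result.

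The authors' deposited table gave its own edgeR result, with 298 called up and 517 called down at a false discovery rate of 0.01 and a fold of 2. With 1 library per group such values rest on an assumed spread, which is not given in the sources used here. Of the calls in the authors' deposited table, 600 of 815 had a mean under 5 CPM. Among those at 5 CPM or more, the authors' deposited table called 50 genes up and 165 down, and 50 and 161 of these were also at least 2-fold higher or lower here. Both rest on the same counts of the same 2 libraries and on a 2-fold limit, so this overlap is no independent check. In the authors' deposited table acs-2 had a log2 ratio of -2.46 with an edgeR false discovery rate of 5.906e-25, daf-2 had -0.15 with 0.778 and sod-3 had 0.27 with 0.634.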

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

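Removal of the length trend, leaving out heat shock list members and leaving out near-identical copies were added after seeing the data; the other alternatives were planned. No paired analysis was possible because each group has 1 library, and for that reason no library could be left out. Scaling alternatives shifted the median of all genes by -0.01 to 0.07 on the log2 scale. The 51 higher and 161 lower genes became 289 and 501 at a minimum of 1 CPM, 1 and 52 at 20 CPM, 944 and 1541 without a minimum, 246 and 703 at 1.5-fold, and 0 and 9 at 4-fold. These shifts follow from what each rule admits. With the length trend removed, 100 genes were lower, of which 95 were also lower in the original count. For the insulin/IGF-1 core the median of -0.03 became 0.01 (0.009) with total counts, 0.01 (0.010) without the 20 most abundant genes and 0.041 with FPKM, and its percentile became 2.28 with length matched. The daf-16 dependent list went from -0.53 to -0.46 with FPKM, -0.31 with the length trend removed, -0.73 over members at 10 CPM, -0.71 as a mean and -0.15 without heat shock list members. Heat shock genes went from -0.53 to -0.49 with total counts (-0.491) or without the 20 most abundant genes (-0.489), -0.46 with FPKM (-0.459), -0.36 with the length trend removed, -0.64 as a mean and -0.20 without near-identical copies. The yolk protein median of 0.20 became 0.231 with total counts, 0.183 with upper quartile scaling, 0.233 without the 20 most abundant genes and 0.263 with FPKM. The infection response median became -0.12 at 10 CPM. The sperm median of 0.80 became 1.21 with the length trend removed and 0.17 at 10 CPM, and the oocyte median of 0.35 became 0.382 with total counts, 0.384 without the 20 most abundant genes and 0.414 with FPKM. The ribosomal protein median turned from -0.17 to 0.09 with the length trend removed. Except where a rule or the scaling itself sets the shift, the cause was not tested. Of 1736 other values for named genes, 1559 stayed within their counting interval. A called value lay at least 2-fold from 1 and the alternatives reuse the same 2 libraries, so a change of sign was hardly possible, and 0 occurred. The lack of replicates limits every value.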

Other observations

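Protein families in the deposited Pfam annotation were placed beside the lists fixed in advance, with which some share genes. Of 189 families, 33 lay below percentile 2.5 and 18 above 97.5 of random lists matched on expression and length. If genes were independent, 4.73 on each side would be expected, but genes regulated together are not. The transthyretin-like family had a median log2 ratio of -0.55 over 49 genes, with 5 at least 2-fold lower and 0 higher, and genes with a ShK toxin-like domain had -0.61 over 32 genes, with 7 lower. Genes with a CUB-like domain, many of them induced by pathogens, had -0.34 over 36 genes, with 8 lower and 0 higher. Families with secreted members were mixed, as the trypsin inhibitor-like domain had -0.55, below the range of random lists, while collagens at -0.05 and astacin proteases at -0.06 lay inside it. The Hsp70 family had -0.35 over 12 genes and the Hsp20 family -0.54 over 17 genes, and both overlap the heat shock list. Of the chemoreceptor families, Srw had -0.43 over 26 genes and Str -0.70 over 14 genes, of which 4 were lower and 1 was higher, and Srx, with 10 genes and a wide random range of -0.46 to 0.37, had 0.06 (0.065).

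The protein-tyrosine phosphatase family had a median of 0.53 over 76 genes, with 24 at least 2-fold higher and 0 lower. The major sperm protein domain had 0.78 over 76 genes, with 25 higher and 2 lower, and overlaps the sperm list through its msp genes. How far the other families of this paragraph overlap the sperm list was not checked, so they may repeat its result. Dual specificity phosphatases at -0.13 and histidine phosphatases at -0.03 lay inside the range of random lists, with 0 higher in both. Calcineurin-like phosphoesterase genes had 0.26 over 47 genes with 6 higher, and protein kinase domain genes had 0.10 over 236 genes, with 17 higher and 1 lower. The Piwi family, Argonaute proteins of small RNA pathways, had 0.26 (0.255) over 19 genes, and the Pumilio RNA-binding family had 0.28 over 10 genes.

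Matching on length was fixed before the data were examined, but its use as a test of a cause, and all other tests in the next paragraphs except that of males, were chosen after the result was seen. With 1 library per group, none of them separates EA from the cultures or the library preparation.

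Short transcripts had lower ratios than long ones. A difference in how the libraries retained short molecules may account for the lists whose medians lie inside the range of random lists of equal length, which are the ribosomal protein list at percentile 81.3 and the respiratory chain, insulin-like peptide and lipid-binding lists, the lowest at percentile 9.53. The random lists could draw the ribosomal protein genes themselves, so percentile 81.3 alone does not decide the question for that list. For the respiratory chain, the place inside the random range holds for the fixed list only. The KEGG pathway of oxidative phosphorylation had -0.142 over 116 genes, below its random range of -0.135 to -0.024, at percentile 1.48 with length matched. The same trend did not account for the whole of the neuropeptide and lysozyme, caenacin and saposin lists, which stayed at percentile 0.12 or below with length matched, although the median of the latter was -0.24 with the trend removed against -0.54 before. A smaller share of neuronal RNA would lower neuron markers as much as neuropeptides, yet their length-corrected median was -0.10 against -0.38 for neuropeptides. The bootstrap 95% interval over genes was -0.20 to -0.03 for neuron markers, without the spread between cultures. An effect of EA, a difference between the cultures and library preparation other than the length trend all remain open for both lists, and the neuronal share test does not bear on the lysozyme, caenacin and saposin list.

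Heat shock transcripts were lower with EA, with a median of -0.53 against a central 95% of -0.16 to 0.06 in random lists of equal expression and length, so the length trend is not the whole cause. Reads shared between near-identical copies could weigh the hsp-16 and hsp-70 pairs too heavily, and the 18 members without such a copy had a smaller median of -0.20, still at percentile 0.11. Handling or temperature before harvest cannot be told apart from EA, because the number of libraries per group is 1 and heat shock genes respond to handling and temperature. A lower stress state with EA and a more stressed control culture both remain open.

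Sperm transcripts were higher with EA. If males in the EA culture were the cause, male-specific markers would be higher by at least the 1.74-fold of the sperm list's median. Their summed ratio was 0.983 (95% counting interval 0.888 to 1.09, 787 and 747 counts), and 1.00 without the most abundant one, try-5. The sum was led by try-5 (402 and 374 counts) and cwp-4 (187 and 154). Of the scarce markers, pkd-2 had 12 and 33 counts, cwp-2 had 12 and 0, and cwp-1 and cwp-3 had 0. Most marker counts may thus not come from males, so the sum cannot exclude a few males in the EA culture. Larval progeny would raise moulting and larval cuticle genes, whose median was -0.24 (bootstrap 95% interval over genes -0.47 to -0.12). A larger germline share alone would raise germline lists alike, but the length-corrected median was 1.21 (1.01 to 1.32) for sperm, 0.34 (0.335) for oocyte and 0.20 for germline genes. This rests on the short msp, nspd and ssp families, at 1.39 corrected and 0.88 uncorrected. The 10 sperm members at 10 CPM or more go the other way, with an uncorrected median of 0.17 against 0.35 for the oocyte list. For members outside the families, at 0.45 (0.19 to 0.96), a germline share cannot be told apart from a sperm-specific difference. These intervals resampled genes, and copies that share reads are not independent, so the interval of the whole sperm list is too narrow. The length trend was fitted on genes at 5 CPM or more, while many sperm members are scarcer. Random lists of equal expression and length had a median of -0.23, so the correction of the sperm median from 0.80 to 1.21 may be too large. Hypotheses that stay open are a few males in the EA culture and a difference in reproductive stage or remaining sperm between the cultures. The latter, from EA or from timing, was not tested.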
